A study of Mus musculus with 44 samples.

How the data were processed

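The study measured where proteins and histone marks sat on DNA in KH2 cells, a mouse embryonic stem cell line, before and during treatment with retinoic acid, which starts neuronal differentiation of such cells. Chromatin was crosslinked, sheared and immunoprecipitated, and each precipitated sample was hybridized together with its input DNA to a custom Agilent tiling array (ChIP-chip). Per the labels, the immunoprecipitated DNA carried Cy5 and the input carried Cy3. There were 44 arrays for 9 antibodies: H3K4me3, a mark of active promoters, H3K27me3, the mark laid by the Polycomb complex PRC2, SUZ12, a subunit of PRC2, RNA polymerase II, the retinoic acid receptors RARα, RARβ and RARγ, their partner RXRα, and the corepressor NCoR.

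The deposited value of each probe is the authors' log2 ratio, made with limma 3.4.3 according to the tools listed with the labels. The sources used here state neither the background correction nor the normalization, and scanner output was not used here. The values were taken as log2 of precipitated DNA over input from their range, which ran from -8.18 to 7.90 over all arrays, and because limma returns ratios on that scale. Array medians lay between -0.10 and 0.01, so the authors had centred or normalized each array. Such values give enrichment relative to the rest of the array, and a change shared by every probe of an array cannot be seen in them. Between 102015 and 102935 of the 102946 probes had a value on each array. For arrays, the number of replicates limits the precision.

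Probe names carry chromosome, position and strand. The genome build was checked from the 85 gene-named regions of 10 kb on the array: 67 of the 80 whose symbol was found in the annotation were centred within 100 bp of that gene's start site in NCBIM37 (mm9). Coordinates and genes are those of NCBIM37 and GENCODE release M1. The array also tiles the 4 Hox clusters and 10 control regions.

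Each array was centred on its median, with no loess or quantile step. Probes were averaged into non-overlapping windows of 1 kb with at least 3 probes, which left 2357 windows: 1333 in the Hox clusters, 916 in gene-named regions and 108 in control regions. Arrays of each antibody were fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, time group as the only term), and each time was compared with uninduced cells, two-sided, with the Benjamini-Hochberg adjusted p held under 0.05 over all windows. Groups of 1 array at 4, 8 and 36 h were assumed to vary like the replicated groups of the same antibody. Start-site values are means over the windows within 1 kb of an annotated transcription start site, and limma was run on these as well.

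Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 10 lists within an antibody and time, and with fry. The lists were written from general knowledge before the data were examined: anterior (paralogue groups up to 4), central and posterior Hox genes, Hox non-coding transcripts, genes beside the clusters, retinoid targets, pluripotency, neural, mesoderm and endoderm, housekeeping and fibroblast genes. Matched by symbol, the array held windows of 12 anterior, 11 central and 16 posterior Hox genes, 7 non-coding transcripts, 6 neighbours, 15 retinoid targets, 2 pluripotency, 2 neural, 1 mesoderm and endoderm, 2 housekeeping and 0 fibroblast genes, so feeder cells could not be assessed. Genes that the annotation holds under another symbol were not counted. The non-coding transcripts matched were Hoxb3os and microRNAs, so that list does not stand for other long non-coding transcripts of the clusters. The array's control genes (9 with a start site, such as Gapdh) and groups of chromatin regulators were put together after the region labels were seen. All 39 Hox protein-coding genes together formed the planned test per antibody. Antibodies with 1 array per group (RNA polymerase II, SUZ12, NCoR and RXRα) have no test: the median change over a list was set against 10000 random window sets of the same size matched on level, as a description of those arrays. A window counted as enriched when it was at least 1 on every array of a group.

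The models, lists, most alternatives and the rule for named genes were also set before the data were examined. The rule was to name, for each comparison at 24 h, the 5 windows with the largest change in each direction among those past the threshold, or otherwise those with the smallest p, given as values, and the 2 members of each list with the largest absolute change. For antibodies without replicates it named the 5 windows with the largest change in each direction among those at least 1 on either array. Any list member may be named beside these.

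Samples were grouped by their titles. Of the labels, 1 RNA polymerase II array titled 4 h has 8 h among its characteristics, and 1 uninduced RARβ array has 24 h there. The series text speaks of 0 to 24 h, while titles and characteristics also hold 36 h. The labels do not say whether replicates came from separate cultures, so they may be technical. The first RARα uninduced replicate was not analysed here. The RARβ arrays form 3 pairs by replicate number: the arrays' deviations from their group means correlated across windows at 0.26, 0.43 and 0.16 within a number, and best within it each time, so numbers were taken to pair these samples, and the block left the count of windows at 0. H3K4me3, H3K27me3, RARα and RARγ share just 2 numbers between the groups, which is too few to establish pairing. Within a number the same correlation was 0.64 for H3K4me3, 0.42 for H3K27me3, 0.23 and 0.14 for RARα and -0.03 and -0.02 for RARγ. The deviations of 2 arrays mirror each other, so the value for each mark is a single comparison. The main fits held no block, so a difference between numbers went into their error.

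Alternatives were values as deposited, equal median absolute deviation, quantile normalization, the median of the probes of a window, single probes, a filter on low windows, 1 fit over all antibodies, a fit of just the 2 groups compared, a block for replicate number, and leaving out each replicate. Windows of 10 kb with at least 30 probes, start sites as features, centring on the control regions and removal of a smooth trend on GC content (lowess, span 0.5) were added after the data were seen. The calculation was tested on simulated data with 200 windows shifted at 24 h. Each simulated array was the mean of an antibody's uninduced arrays plus independent normal noise with the spread fitted for each window. At a log2 change of 1 it recovered 1 for H3K4me3, 34 for H3K27me3, 156 for RARα, 130 for RARβ and 96 for RARγ. At a change of 2 it recovered 184, 199, 198, 199 and 199. The simulation held no correlation between windows and no difference in level between replicate arrays, so these counts do not measure recovery on the real arrays. Sites of the DR5 type, 2 receptor half-sites of 6 bases spaced by 5 bases, were searched in the genome sequence. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table, version 1.17.8.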

Results

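The series asked how retinoic acid changes the chromatin of the mouse Hox clusters, the gene arrays that set position along the body axis, and where retinoid receptors bind there. KH2 embryonic stem cells were sampled uninduced and after retinoic acid. H3K4me3 and H3K27me3 were measured uninduced (2 arrays each), at 4 h (1), 8 h (1), 24 h (2) and 36 h (1). RNA polymerase II was measured on 1 array at each of these times, and SUZ12, NCoR and RXRα on 1 array each uninduced, at 2 h and at 24 h. RARα had 2 uninduced and 3 arrays at 24 h, RARβ had 3 and 3, and RARγ had 3 and 2. Values are log2 ratios of precipitated DNA over input, centred on each array's median, and errors are SD over arrays. The 1 kb windows of replicate arrays correlated at 0.82 and 0.84 for H3K27me3 and at 0.50 and 0.58 for H3K4me3, but at 0.16 to 0.31 for RARα, 0.07 to 0.28 for RARβ and -0.00049 to 0.24 for RARγ, across windows, which are not independent replicates.

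In uninduced cells H3K27me3 covered all 4 Hox clusters. It was at least 1 on both arrays in 227 windows, of which 195 lay in the clusters (61 in HoxA, 44 in HoxB, 39 in HoxC and 51 in HoxD) and 0 of 108 in control regions. At start sites it was highest at Hoxa11, a posterior gene (1.48 ± 0.24, n = 2), and was 1.21 ± 0.08 at Hoxa2 and 1.10 ± 0.42 at Hoxb1, which act in the hindbrain. Gapdh, a housekeeping gene, had -0.42 ± 0.62. SUZ12 was at least 1 in 205 windows of its single uninduced array, and 93 of them were H3K27me3 windows, against 19.7 expected of independent lists. H3K4me3 was at least 1 in 42 windows, 3 of them in the clusters, and shared 0 windows with H3K27me3, where 4.04 were expected (Fisher's exact p = 0.0296, with windows taken as independent). At 24 h the 2 marks also shared 0 windows, where 2.75 were expected (Fisher's exact p = 0.0998). The counts followed the less enriched array of a group: without the second uninduced array H3K4me3 had 292 such windows and H3K27me3 503. The 0 shared windows do not show that the marks exclude each other, since joint signal under 1 was not counted. At the start sites of Meis1 and Meis2, uninduced H3K4me3 had 0.67 ± 0.39 and 0.65 ± 0.55 and H3K27me3 1.06 ± 0.34 and 0.80 ± 0.23. Neighbouring windows were also not independent (correlation 0.84 and 0.83 on the uninduced H3K27me3 arrays).

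After 24 h of retinoic acid, H3K27me3 was lower at anterior genes of HoxA and HoxB and higher at posterior genes. It went from 1.21 ± 0.08 to 0.32 ± 0.23 at Hoxa2 (n = 2 each), from 1.17 ± 0.20 to 0.30 ± 0.58 at Hoxb2 and from 1.10 ± 0.42 to 0.39 ± 0.05 at Hoxb1. The log2 change was -0.58 at Hoxa4, -0.61 at Hoxb4 and, among central genes, -0.69 at Hoxb5 and -0.43 at Hoxa5. Both arrays at 24 h lay below both uninduced arrays at Hoxa2, Hoxa3 and Hoxa4 and at the 4 anterior genes of HoxB, where chance gives 16.7% in 1 direction for a gene. These genes share the same 4 arrays, on which neighbouring windows correlated at 0.77 to 0.88, so they are not separate trials. In HoxD the anterior genes Hoxd1 and Hoxd3 had changes of 0.19 and 0.23. Of 16 posterior genes, 14 were higher at 24 h, among them Hoxa11 (1.48 ± 0.24 to 1.81 ± 0.22) and Hoxc12 (1.27 ± 0.30 to 1.66 ± 0.16), while Hoxb13 had a change of -0.40. The changes depended on single arrays: without 1 of the 4 arrays they ran from -1.05 to -0.73 at Hoxa2, -1.28 to -0.46 at Hoxb2, -1.01 to -0.42 at Hoxb1, -1.11 to -0.27 at Hoxb5, -0.76 to -0.049 at Hoxb13, 0.17 to 0.51 at Hoxa11, 0.18 to 0.60 at Hoxc12, -0.82 to -0.35 at Hoxa4, -0.86 to -0.35 at Hoxb4, -0.58 to -0.28 at Hoxa5, 0.10 to 0.27 at Hoxd1 and 0.048 to 0.41 at Hoxd3.

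**Figure D1:**
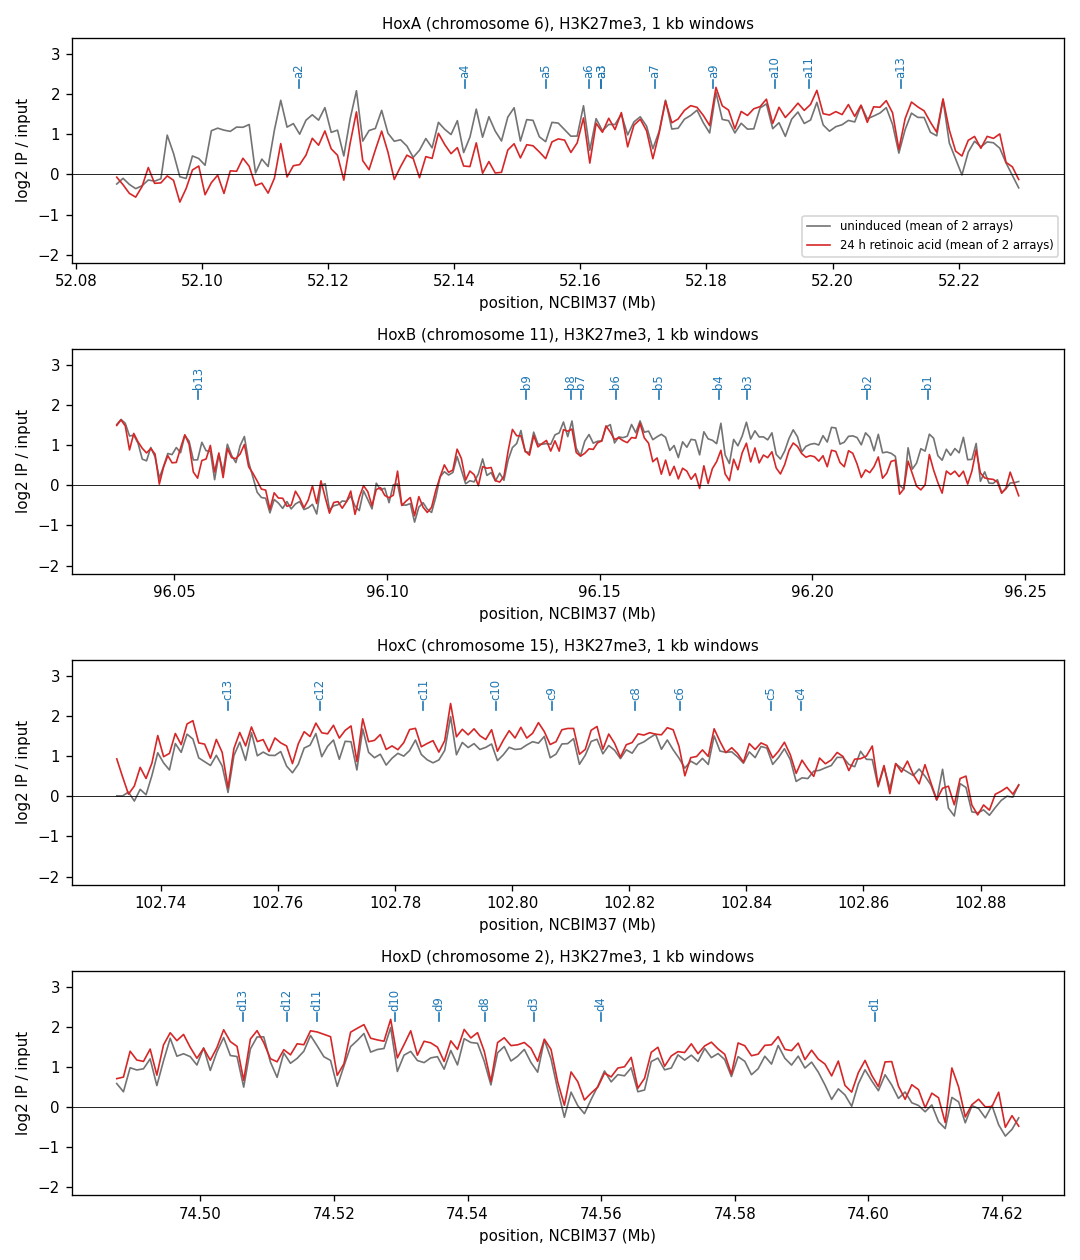
H3K27me3 across the 4 Hox clusters. Each panel plots the log2 ratio of precipitated DNA over input in 1 kb windows against position, as the mean of 2 uninduced arrays (grey) and of 2 arrays at 24 h (red), with start sites marked in blue by gene number. The red line lies below the grey one around a2 to a5 in HoxA and b1 to b5 in HoxB, and close to or above it over HoxC and HoxD.

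By limma's camera test the anterior Hox windows fell at 24 h relative to the other windows (mean log2 change -0.22, median -0.11 over 67 windows, 38 of them lower, adjusted p = 8.34e-05) and the posterior Hox windows rose (median 0.24 over 57 windows, 52 of them higher, adjusted p = 2.87e-04). Neither call held once the correlation was estimated (adjusted p = 0.793 with an estimated correlation, both lists), and neither passed limma's fry (adjusted p = 0.703 each). Without single arrays the anterior list kept its call, with medians from -0.27 to -0.046. Without the second uninduced array the posterior list had a median of 0.09 and an adjusted p of 0.0919 by limma's camera. All 39 Hox genes together did not pass, with a median of 0.09, a mean of -0.03, a test direction downward and no pass at 0.05 in limma's camera (without the second uninduced array the median was -0.09 and passed, and without the first it was 0.18 with a test direction upward), and the 11 central genes had a median of -0.04 (adjusted p = 0.223).

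**Figure D2:**
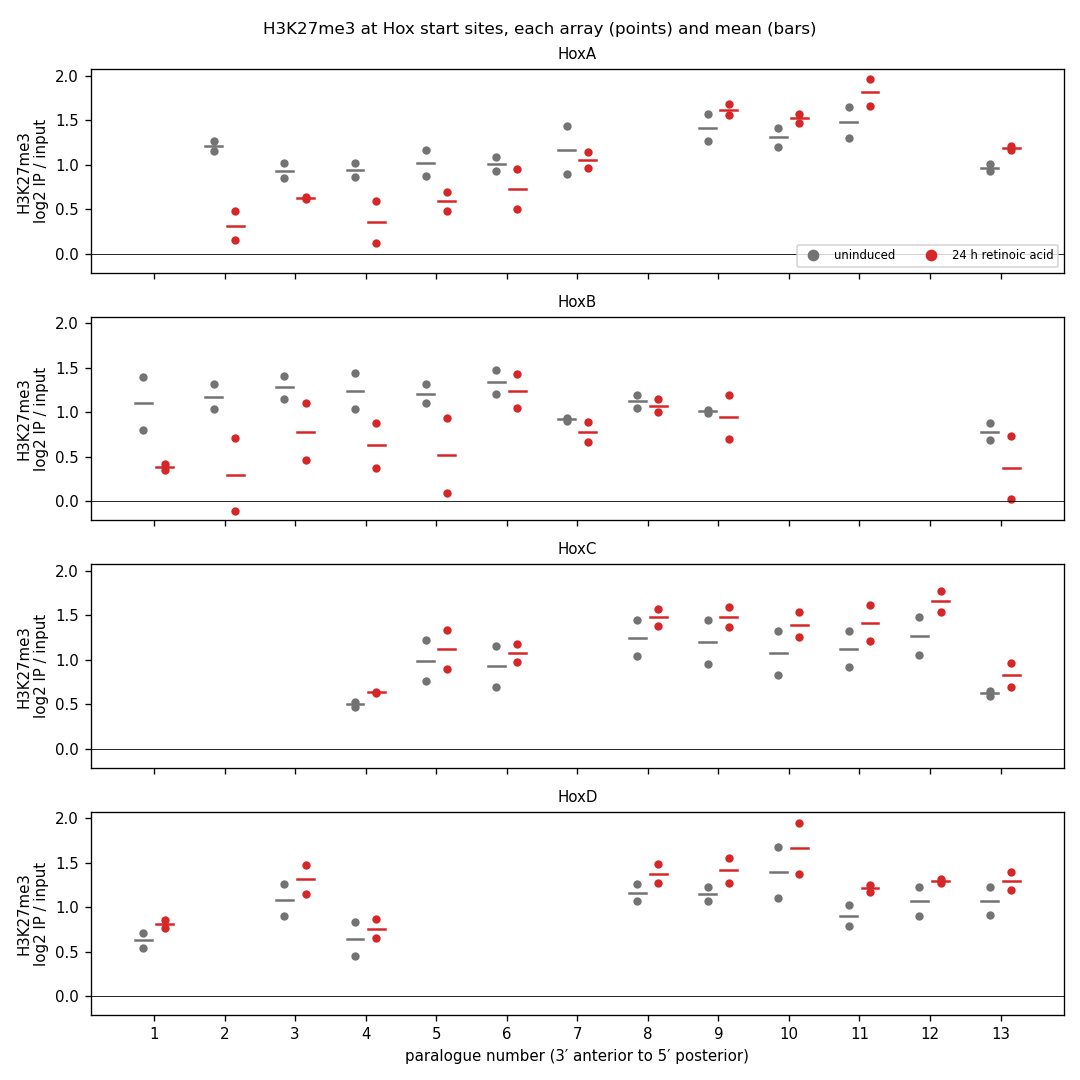
H3K27me3 at the start sites of 38 Hox genes. Points are single arrays and bars their mean, uninduced in grey and at 24 h in red, against paralogue number from anterior to posterior, with the log2 ratio on the vertical axis. At Hoxa2 the mean was 1.21 uninduced and 0.32 at 24 h, and at Hoxa11 it was 1.48 and 1.81.

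Retinoid target genes went both ways. Cyp26a1, whose enzyme degrades retinoic acid, went from 0.85 ± 0.12 to -0.05 ± 0.08 (n = 2 each), and its neighbour Cyp26c1 from 0.31 ± 0.13 to -0.19 ± 0.32. Cdx1, a homeobox gene that regulates Hox genes, had 0.36 ± 0.20 and then -0.31 ± 0.05, and Rarb, the gene of RARβ, had 0.31 ± 0.21 and then -0.25 ± 0.24. Cdx2 and Egr2 had changes of 0.17 and 0.20. The list did not pass: its median was 0.008 and its mean -0.11, with a test direction downward (59 windows, limma camera adjusted p = 0.051). It did pass with the replicate block (0.0435), as deposited (0.0458), after quantile normalization (0.0193), with the median of the probes (0.0424), with control-region centring (0.0346) and without the first uninduced array (0.00902), all adjusted p of limma's camera. With all arrays it had adjusted p = 0.793 with an estimated correlation and adjusted p = 0.597 by limma's fry. The genes beside the clusters had a median of 0.16 (adjusted p = 0.166 by limma's camera), with the homeobox genes Evx1 (1.08 ± 0.41 to 1.63 ± 0.01) and Evx2 (1.29 ± 0.17 to 1.66 ± 0.11) highest. Non-coding transcripts had a median of 0.09 and a mean of -0.10 (adjusted p = 0.21), and within them Mir10a and Hoxb3os had changes of -0.53 each. Neural genes had -0.13 (adjusted p = 0.051, and the same 0.0435, 0.0458, 0.0193 and 0.0346 with the block, as deposited, after quantile normalization and with control-region centring, but adjusted p = 0.793 with an estimated correlation and 0.703 by limma's fry), with Pax6 at -0.25 and Sox3 at 0.10, the latter of opposite sign without the first uninduced array (-0.06) or the second array at 24 h (-0.09). Pluripotency genes (Sox2 -0.07, Fgf4 0.07) had adjusted p = 0.864 and housekeeping genes (Gapdh -0.09) 0.596, both from limma's camera. Without the first array at 24 h the housekeeping list (median -0.28, adjusted p = 0.0176) and the genes beside the clusters (0.27, adjusted p = 0.0305) passed limma's camera, while with all arrays both had adjusted p = 0.793 with an estimated correlation.

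The changes at these start sites depended on single arrays too. Without 1 of the 4 arrays they ran from -0.73 to -0.27 at Cyp26c1, 0.26 to 0.84 at Evx1, -0.80 to -0.26 at Hoxb3os, -0.81 to -0.25 at Mir10a and -0.41 to -0.098 at Pax6, and from -0.98 to -0.81 at Cyp26a1.

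Single windows did not pass for H3K27me3: limma called 0 of 2357, with 93 at an unadjusted p under 0.05 (20 higher, 73 lower) against 118 by chance, 0 with a replicate block and 0 of the start sites, also adjusted over the list alone, where the smallest adjusted p was 0.209 among the Hox genes and 0.063 among retinoid targets. The count depended on single arrays: it was 1 without the first array at 24 h, 4 without the second uninduced array and 16 (5 higher, 11 lower) without the second array at 24 h. The lower windows with the smallest p included 1 in an exon of Hoxa2 and Hoxa3 (chromosome 6, 52113000 to 52113999, 1.18 ± 0.42 to -0.06 ± 0.04) and 2 beside Cyp26a1 (chromosome 19, 37770000 to 37770999, 0.66 ± 0.37 to -0.61 ± 0.02, and 37771000 to 37771999, 0.87 ± 0.07 to -0.30 ± 0.02). The higher ones were 3 windows at Lef1, a transcription factor of Wnt signalling (chromosome 3, changes of 0.91, 1.14 and 0.96), and 2 in exons of Setd1a, a histone methyltransferase gene (chromosome 7, changes of 1.06 and 0.83). The Setd1a windows lay below the array median at both times (-1.27 ± 0.82 to -0.20 ± 0.56 and -1.15 ± 0.10 to -0.31 ± 0.48), so they were less depleted at 24 h and not enriched. In windows of 10 kb, a setting chosen after the data were seen, limma called 2 of 306: the window of Cyp26a1 fell by 0.94 and a window beside Lef1 rose by 0.93 (adjusted p = 0.0463 each, and 0.0781 with arrays scaled to the same spread).

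H3K4me3 at 24 h was higher than uninduced at Hoxb1 and at Cyp26a1, within a wide spread between arrays. Hoxb1 had 0.24 ± 0.11 uninduced and 0.87 ± 0.82 at 24 h (n = 2 each), and Cyp26a1 0.32 ± 0.65 and 1.58 ± 1.13. Hoxb8 and Hoxb7, central genes, had changes of 0.46 and 0.36, and Cdx1 0.39. Among pluripotency genes, Fgf4, which encodes a growth factor of stem cells, had 1.32 ± 1.22 and then 0.39 ± 0.42, and Sox2, a core pluripotency factor, 1.75 ± 1.26 and then 1.23 ± 0.89. Gapdh had 1.39 ± 1.37 and then 1.19 ± 1.01. Without 1 of the 4 arrays the changes ran from 0.049 to 1.21 at Hoxb1, 0.46 to 2.06 at Cyp26a1, 0.045 to 0.87 at Hoxb8, 0.14 to 0.63 at Cdx1 and -1.79 to -0.058 at Fgf4.

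The pluripotency windows fell in H3K4me3 by limma's camera test (median -0.65, 7 of 7 windows lower, adjusted p = 0.00477, and adjusted p = 0.856 with an estimated correlation), but not by limma's fry (adjusted p = 0.953). The median was 0.10 without the first uninduced array and -0.15 without the second array at 24 h, and neither passed, and Sox2 alone then had changes of 0.38 and 0.12. These fits set first and second arrays unevenly against each other, and levels differed between them. On the first arrays the mean over these windows was 2.44 uninduced and 1.36 at 24 h, and on the second arrays 0.68 and 0.39. The anterior Hox list did not pass (median 0.03, mean 0.13, limma camera adjusted p = 0.105) but did with arrays of equal spread (0.0118), after quantile normalization (0.0103) and with 3 other settings (control-region centring, where its median was -0.0042, GC trend removal and the replicate block), and without the second uninduced array (0.0245) or the second array at 24 h (0.0409). With all arrays it had adjusted p = 0.856 with an estimated correlation and adjusted p = 0.953 by limma's fry. Over all Hox genes the median was -0.006 and the mean 0.05, which did not pass limma's camera at 0.05, but did with the GC trend removed (median 0.014) and without the second array at 24 h (0.08). The other lists had limma camera adjusted p of 0.352 or more, and their members with the largest absolute changes included Evx1 (-0.19) and Skap2 (-0.14) beside the clusters, Hoxb3os (0.23) and Mir10b (-0.22) among non-coding transcripts, Hoxd12 (-0.26) and Hoxb13 (0.18) among posterior genes, Sox3 (-0.39) and Pax6 (-0.02) among neural genes. Medians were below 0 and means above 0 for the non-coding and retinoid target lists.

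Medians of several H3K4me3 lists shifted once 1 array was left out, in directions that depended on the array. Levels differed between replicate numbers. At the start sites of the control genes the first arrays had 1.97 uninduced and 1.58 at 24 h, and the second arrays 0.40 and 0.43. Leaving out 1 array therefore compares numbers as well as times, and the shifts below are not changes with retinoic acid alone. The retinoid targets had 0.25 without the first uninduced array, 0.18 without the second array at 24 h and -0.15 without the first. The housekeeping list had 0.70 without the first uninduced array, -1.23 without the second and -0.93 without the first array at 24 h. The central Hox list had 0.20 without the second array at 24 h and the posterior one -0.14 without the first. With all arrays, limma's camera with an estimated correlation gave the Hox lists adjusted p = 0.856 and the 2 others adjusted p = 0.915. By limma's fry each had adjusted p = 0.953.

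Limma called 0 of 2357 windows for H3K4me3 at 24 h, with 14 at an unadjusted p under 0.05 (6 higher, 8 lower) against 118 by chance. It called 0 start sites, also adjusted over the list alone, and 12 windows (6 higher, 6 lower) with replicate number as a block. A count so far below chance means that the fit without a block could call little, so its 0 does not show an unchanged mark. The windows with the smallest p that were higher included an exon of Lnp beside HoxD (change 0.92) and intergenic windows in HoxC, HoxD and HoxB (1.11, 0.86 and 0.77). In that order their means went from -0.50, -0.74, -0.61 and -0.64 uninduced to 0.42, 0.36, 0.25 and 0.13 at 24 h. They were therefore not enriched by the threshold of 1 at either time. The windows that were lower lay in introns of Cdx4 (-1.67), in an exon of Cyp26b1 (-0.82) and between genes in HoxC (-1.09 and -0.87) and HoxD (-0.98). Their uninduced means were at most 0.93.

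Earlier and later times addressed how fast the marks respond, each with 1 array. H3K27me3 at Hoxa2 was 1.21 uninduced, 0.89 at 4 h, 0.69 at 8 h, 0.32 at 24 h and 0.24 at 36 h. At Cyp26a1 it was 0.85, 0.75, 0.59, -0.05 and 0.47. Hoxa11 had 1.48, 1.40, 1.65, 1.81 and 1.03. Within arrays, the mean of posterior minus anterior Hox windows was 0.18 and 0.17 on the uninduced arrays, 0.31 at 4 h, 0.40 at 8 h, 0.69 and 0.51 at 24 h and 0.37 at 36 h.

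By limma's camera the anterior Hox list passed downward in H3K27me3 at 4 h (median -0.14, adjusted p = 0.00386, and adjusted p = 0.897 with an estimated correlation), while the posterior list passed upward at 8 h (median 0.34, adjusted p = 3.81e-05, and adjusted p = 0.963 with an estimated correlation). The anterior list at 8 h had a median of 0.11, with 44 of 67 windows higher, and did not pass (adjusted p = 0.892). Over all Hox genes the median was -0.057 at 4 h, 0.20 at 8 h (134 of 169 windows higher) and -0.50 at 36 h (155 lower), each past 0.05 in limma's camera and none with an estimated correlation. At 36 h anterior, central, non-coding and posterior lists passed downward (medians -0.63, -0.56, -0.51 and -0.39, adjusted p from 7.51e-12 to 1.86e-05, and adjusted p = 0.483 with an estimated correlation for each). The pluripotency list passed upward at 4 and 36 h (medians 0.63 and 0.64, adjusted p = 0.0361 and 0.0282, and adjusted p = 0.897 and 0.483 with an estimated correlation), and the neural list passed downward at 36 h (-0.43, adjusted p = 0.0282, and adjusted p = 0.516 with an estimated correlation). The array at 36 h had a lower spread (median absolute deviation over windows 0.32, against 0.78 and 0.69 uninduced) and a correlation of 0.57 with GC content, against 0.05 and 0.14. The array at 4 h also stood apart in both (0.42 and 0.40), and that at 8 h had 0.65 and 0.28. None of these lists passed limma's fry (smallest adjusted p = 0.303). With 1 array at each of these times, a change with time cannot be told apart from a property of that array.

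No H3K27me3 window passed in limma at 4 h (37 at an unadjusted p under 0.05), 8 h (38) or 36 h (214, of which 158 were lower). Without the second uninduced array there were 11 at 8 h and 34 at 36 h, all lower, and at 36 h there were 45 (30 higher, 15 lower) with arrays of equal spread and 10 in a fit of just the 2 groups.

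**Figure D3:**
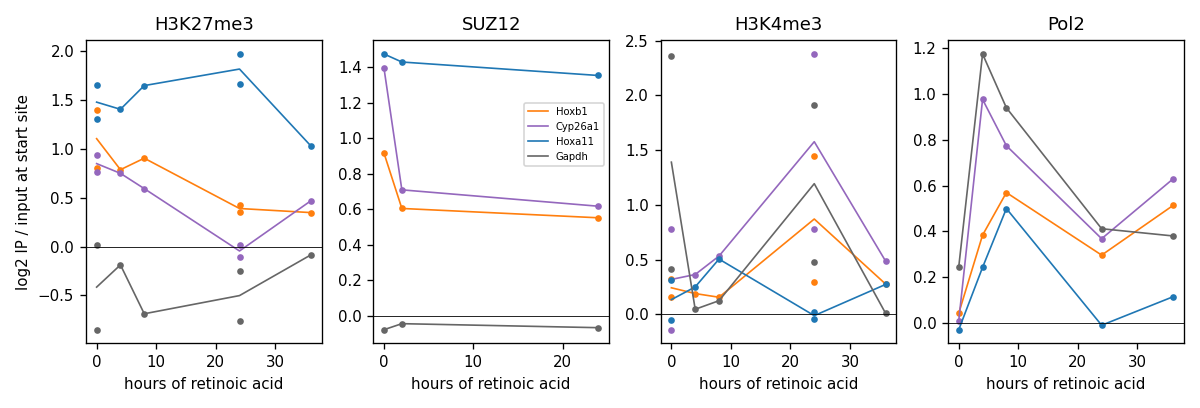
Levels at 4 start sites over time for 4 antibodies. The horizontal axis gives hours of retinoic acid, the vertical axis the log2 ratio, points are arrays and lines join their means. H3K27me3 at Cyp26a1 went from 0.85 uninduced to -0.05 at 24 h, SUZ12 at Cyp26a1 from 1.39 to 0.71 at 2 h, and RNA polymerase II was 1.18 at Gapdh and 0.98 at Cyp26a1 at 4 h.

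H3K4me3 at 4, 8 and 36 h stood apart from the uninduced and 24 h arrays. At the start sites of the array's control genes it was 0.07, 0.14 and 0.18, against 1.97 and 0.40 uninduced and 1.58 and 0.43 at 24 h, and its correlation with GC content was 0.60, 0.47 and 0.62, against 0.21 to 0.33 on the other arrays. Gapdh had 0.05, 0.13 and 0.008. By limma's camera the housekeeping list passed downward at each time (medians -1.18, -1.14 and -1.11, adjusted p = 5.49e-04, 0.0143 and 0.00112, and adjusted p = 0.666, 0.80 and 0.808 with an estimated correlation). The pluripotency list did too (-0.62, -0.98 and -0.68, adjusted p = 0.00738, 0.00835 and 0.0017, and the same 3 values with an estimated correlation). The posterior Hox list passed upward (0.25, 0.17 and 0.26, adjusted p = 5.49e-04, 0.0355 and 9.72e-04), as did the anterior (0.16, adjusted p = 5.49e-04) and central lists (0.19, adjusted p = 0.00738) at 4 h, with adjusted p of 0.485 or more with an estimated correlation. All Hox genes together had medians of 0.20, 0.11 and 0.18, each past 0.05 in limma's camera and none with an estimated correlation. No list passed limma's fry (smallest adjusted p = 0.843). Limma called 0 windows at each time, with 35, 37 and 22 at an unadjusted p under 0.05, and 2 at 8 h with centring on the control regions. Time and this set of arrays cannot be told apart.

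SUZ12 was lower over the Hox clusters on the 24 h array than on the uninduced one. The median change over Hox windows was -0.27, with 155 of 169 windows lower, below all 10000 matched random sets (their median -0.21). At Cyp26a1 it was 1.39 uninduced, 0.71 at 2 h and 0.62 at 24 h, at Hoxa2 1.18, 0.83 and 0.66, and at Hoxa5 1.39, 1.05 and 0.74. Evx1 had 0.87, 0.85 and 0.87. At 2 h the anterior Hox windows had a median change of -0.12 (percentile 0.2 of the random sets) and the posterior ones -0.07 (85.3). Windows at least 1 numbered 205, 155 and 103, and 96 of the 103 at 24 h were among the uninduced ones.

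The windows lowest at 24 h relative to uninduced for SUZ12 lay in HoxA (chromosome 6: an exon of 5730596B20Rik, -1.12, Hoxa5, -0.92, and an exon of Hoxa9, -0.82) and at Cyp26c1 (-0.97) and Cyp26a1 (-0.87). Those higher included windows in Pax6 (0.34), beside Hoxa11 (0.28) and in exons of Hoxd13 (0.27) and Hoxd11 (0.18). The median of each list tested was below 0 at 24 h, with the genes beside the clusters nearest to 0 (-0.01, percentile 90.4). The control genes had -0.10 (percentile 3.01). Percentiles of other lists included 0.09 for anterior, 2.56 for central and 10.2 for posterior Hox genes, 2.81 for non-coding transcripts, 4.23 for retinoid targets, 1.81 for neural genes, 49.4 for pluripotency and 17.0 for housekeeping genes. With 1 array per time, the spread between cultures is unknown. Other list members with the largest absolute changes were Hoxa4 (-0.49), Hoxb7 (-0.40), Hoxa13 (-0.43), Hoxa10 (-0.39), Mir196a-1 (-0.41), Hoxb3os (-0.41), Skap2 (0.20), Ttll6 (-0.16), Sox3 (-0.31) and Fgf4 (-0.20).

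RNA polymerase II was higher at the start sites of Cyp26a1 and Cdx1 early after induction, and higher at control genes too. The retinoid target list had a median change of 0.21 at 4 h (percentile 74.1 of the matched random sets) and 0.24 at 8 h (96.5), and the control genes 0.57 (100) and 0.45 (99.9). At Cyp26a1 it was 0.009 uninduced, 0.98 at 4 h, 0.77 at 8 h, 0.37 at 24 h and 0.63 at 36 h. Cdx1 had 0.16, 1.03, 0.81, 0.47 and 0.35. Gapdh had 0.24, 1.18, 0.94, 0.41 and 0.38, and the control genes had a mean of 0.04, 0.60, 0.53, 0.17 and 0.23. The arrays at 4, 8 and 36 h had correlations with GC content of 0.51, 0.57 and 0.70, against 0.11 uninduced and 0.26 at 24 h, so time cannot be told apart from this difference between arrays. At 24 h the median Hox change was 0.01 (percentile 94.2), and -0.03 with centring on the control regions. At 4, 8 and 36 h it was 0.12, 0.17 and 0.13 (percentiles 97.8, 99.99 and 100), on the arrays with the higher correlation with GC content. At 24 h the anterior Hox list had a median of 0.05 (percentile 98.7), the pluripotency list -0.02 (38.9) and the retinoid targets -0.001 (54.7). On that array the control genes had 0.20 (100) and the housekeeping list 0.22 (98.9), so the anterior rise was not particular to Hox genes. The windows with the largest changes among the 3 of at least 1 were an exon of Gm15055 (0.41) and of Hoxd8 (0.32), and a window near Sox3 (-0.18).

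NCoR signal at each time, and RXRα signal uninduced and at 24 h, was strongest in intergenic HoxA windows near the transcript Gm15055, on chromosome 6. In the window 52049000 to 52049999 NCoR had 2.27 uninduced, 2.39 at 2 h and 1.54 at 24 h, and RXRα 4.36, 1.32 and 3.94. In the next window NCoR had 1.94, 2.10 and 1.27 and RXRα 3.78, 1.499 and 3.46. These windows ranked 16 and 7 for RXRα at 2 h. For NCoR they were the 2 highest at each time. Uninduced, at 2 h and at 24 h, RXRα also had 2.33, 0.03 and 1.87 near Gm8078 (52073000 to 52073999), 1.76, 0.58 and 1.48 at 52048000 to 52048999, 1.03, 0.06 and 0.76 at 52072000 to 52072999, and 0.09, 1.55 and 1.01 in an intron of Suz12. The RXRα array at 2 h stood apart, with 57 windows of at least 1 against 5 uninduced and 5 at 24 h, a median absolute deviation of 0.40 against 0.24 and 0.24, and correlations of 0.17 and 0.20 with the 2 other arrays, so its lower values cannot be told apart from a property of that array. Over the Hox genes the median change at 24 h was 0.02 for NCoR (percentile 60.2), of opposite sign with the median of the probes (-0.009), and -0.06 for RXRα (percentile 1.92). The RXRα median was -0.025 with centring on the control regions and -0.034 with the GC trend removed. List medians at 24 h farthest from the random sets included these: the neural list had -0.12 for NCoR (percentile 4.29), and for RXRα central Hox genes had -0.13 (1.32), posterior ones -0.09 (2.87) and retinoid targets -0.09 (3.53).

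The receptor antibodies addressed whether RARα, RARβ and RARγ move on or off these regions. The HoxA window with the strongest RXRα signal ranked 1 for RARα at both times and for RARβ uninduced, 2 for RARβ at 24 h and for RARγ uninduced, and 112 for RARγ at 24 h, where the next window ranked 4: RARα had 3.85 ± 0.79 uninduced (n = 2) and 1.63 ± 2.48 at 24 h (n = 3), RARβ 2.70 ± 1.73 and 1.77 ± 2.67 (n = 3 each) and RARγ 1.34 ± 1.29 (n = 3) and 0.40 ± 1.73 (n = 2), a window singled out after its values were seen. At the start site of Hoxb1 RARα had 1.13 ± 0.10 and 1.05 ± 0.26, RARβ 0.53 ± 0.56 and 0.59 ± 0.68 and RARγ 0.45 ± 0.16 and 0.78 ± 0.44. Over the 16 windows with a DR5 site, the usual binding element of these receptors, the mean was 0.18 uninduced and 0.32 at 24 h for RARα, 0.06 and 0.03 for RARβ and 0.07 and 0.16 for RARγ. Single arrays ran from 0.16 to 0.19 and 0.085 to 0.46 for RARα, -0.033 to 0.13 and -0.0082 to 0.069 for RARβ, and -0.11 to 0.21 and 0.061 to 0.26 for RARγ. All RAR and RXRα arrays together had 0.13 there and 0.006 in other windows.

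**Figure D4:**
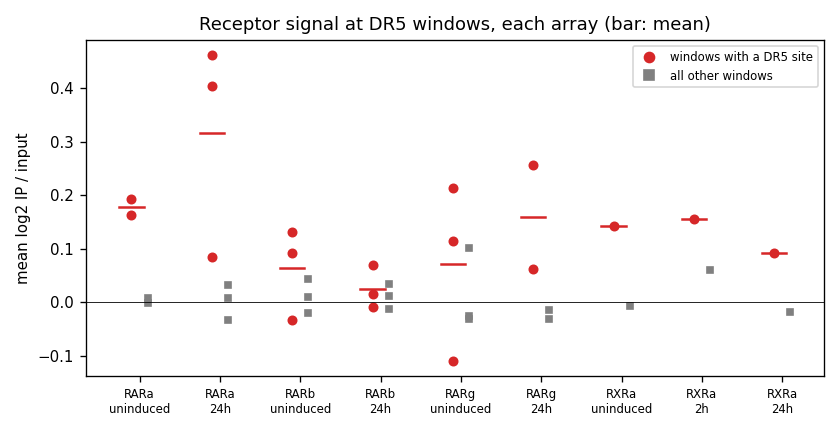
Receptor signal at windows with a DR5 site. Red points give the mean log2 ratio over the 16 windows on each array, with a bar for the group mean, and grey squares the mean over all other windows. RARα at 24 h had the highest group mean, 0.32.

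No list passed limma's camera for a receptor at 24 h. Limma's fry, which does not compare a list with other windows, passed for the RARβ housekeeping list (median -0.05, 2 genes, adjusted p = 0.0298) and for no other list at 24 h. Over the Hox genes the median change was -0.02 for RARα, 0.03 for RARβ and 0.009 for RARγ (mean -0.002), and none passed limma's camera at 0.05, though RARα did with equal spread or quantile normalization and RARβ (0.07) without its first array at 24 h. The smallest list values were 0.689 for RARα, 0.286 for RARβ and 0.245 for RARγ, all adjusted p of limma's camera. Lists whose median and mean differed in sign included the RARα anterior, central and retinoid target lists and the RARγ neighbour, posterior and neural lists, and the RARβ anterior list had a median and mean below 0 with a test direction upward.

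Limma called 0 of 2357 windows for RARα (67 at an unadjusted p under 0.05, 33 of them higher), RARβ (47, 28 higher) and RARγ (94, 25 higher), and 0 start sites, also adjusted over the list alone. By chance 118 windows would have such a p for each receptor. The windows with the smallest p for RARα were higher near Skap2 (0.96) and Sox3 (1.11), in Rarb (1.20), in HoxD (0.64) and in Cbx7 (0.66), and lower in Ezh2 (-1.36), Ruvbl1 (-0.63), Pknox1 (-1.35), Orai3 (-0.82) and HoxC (-0.80). For RARβ they were higher in HoxD (0.88 and 0.67), HoxC (0.54 and 0.63) and HoxB (0.62), and lower in HoxB (-0.76), Cdx4 (-0.52), Trove2 (-0.66) and Sfmbt2 (-0.65). For RARγ they were higher near Ino80 (0.98), in HoxC (1.03), in HoxA (0.88), in Hoxc13 (0.78) and in Pknox1 (0.81), and lower in Kdm6a (-1.29), Lnp (-1.18 and -1.35), near Eed (-0.96) and in HoxA (-0.87). Uninduced, the means in the higher windows of each receptor lay below 0, down to -0.82 (RARγ near Ino80). At 24 h they reached at most 0.92 (RARα in Rarb), so none was enriched by the threshold of 1. No difference between the receptors' changes passed: limma called 0 windows for RARα minus RARβ, RARα minus RARγ and RARβ minus RARγ (63, 72 and 101 at an unadjusted p under 0.05).

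For RARα the list members with the largest absolute change at 24 h included Gapdh (0.08), Hoxa2 (-0.44), Hoxc6 (-0.19), Hoxb5 (-0.14), Skap2 (0.29), Skap1 (-0.19), Mir10b (0.25), Mir10a (0.16), Hoxd12 (-0.33), Hoxc12 (-0.30), Pax6 (-0.10), Sox3 (0.08), Fgf4 (-0.07), Sox2 (0.01), Cdx2 (-0.28) and Rarb (0.18). For RARβ the list members with the largest absolute change at 24 h included Gapdh (-0.0044), Hoxb4 (-0.31), Hoxa2 (-0.28), Hoxc5 (0.25), Hoxa6 (-0.22), Evx2 (0.33), Mtx2 (0.20), Mir10a (-0.20), Mir196a-1 (-0.20), Hoxd12 (0.33), Hoxc12 (0.22), Sox3 (0.07), Pax6 (0.06), Fgf4 (0.27), Sox2 (0.04), Pbx2 (0.23) and Meis1 (-0.17). For RARγ the list members with the largest absolute change at 24 h included Gapdh (0.24), Hoxb1 (0.33), Hoxa6 (-0.23), Hoxa5 (-0.22), Skap2 (0.30), Skap1 (-0.30), Mir196a-1 (-0.22), Mir615 (0.20), Hoxd12 (-0.34), Hoxa10 (-0.25), Pax6 (0.02), Sox3 (-0.02), Fgf4 (0.31), Sox2 (0.08), Cdx2 (0.30) and Rarg (0.24). For RNA polymerase II the list members with the largest absolute change at 24 h included Gapdh (0.17), Hoxb1 (0.25), Hoxa6 (-0.18), Hoxb8 (-0.13), Skap2 (0.17), Evx1 (0.14), Mir196a-2 (-0.21), Mir196b (-0.17), Hoxd10 (0.20), Hoxc12 (-0.19), Sox3 (0.10), Pax6 (0.03), Fgf4 (-0.07), Sox2 (0.02), Cyp26a1 (0.36) and Cdx1 (0.31). For NCoR the list members with the largest absolute change at 24 h included Gapdh (-0.11), Hoxa4 (0.18), Hoxb6 (-0.18), Hoxb5 (-0.17), Ttll6 (-0.32), Mtx2 (-0.24), Mir196a-2 (-0.30), Mir196b (0.24), Hoxc11 (0.24), Hoxc12 (-0.23), Pax6 (-0.15), Sox3 (-0.08), Fgf4 (-0.09), Sox2 (0.03), Cdx1 (0.28) and Cyp26c1 (-0.17). For RXRα the list members with the largest absolute change at 24 h included Gapdh (-0.0032), Hoxb4 (-0.30), Hoxb2 (0.16), Hoxa6 (-0.31), Hoxb5 (-0.23), Mtx2 (0.14), Evx2 (-0.13), Mir615 (-0.44), Mir10a (-0.19), Hoxc9 (-0.54), Hoxd11 (-0.32), Pax6 (-0.11), Sox3 (-0.05), Fgf4 (0.12), Sox2 (-0.09), Cdx2 (-0.45) and Rarb (-0.20).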

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

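The comparisons of 4, 8 and 36 h with 24 h below, the test of array amplitude, the test of SUZ12 occupancy, the test of H3K4me3 loss and the sign of the GC trend were chosen after the result was seen, and the other tests in this part were set before. No group held 4 or more arrays, so no array was tested for being far from its group.

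Gene lists were flagged where limma's camera found that the change from uninduced differed between 24 h and another time, each of which had 1 array. None passed with an estimated correlation (smallest adjusted p = 0.387). For H3K4me3 at 4 h minus 24 h, the median difference was -1.07 for housekeeping genes, 0.28 for posterior Hox genes and 0.22 for all Hox genes. At 8 h it was -1.05 for housekeeping and 0.22 for posterior Hox genes, and at 36 h it was -1.02, 0.27 and, for all Hox genes, 0.16. For H3K27me3 at 4 h minus 24 h it was -0.23 for posterior Hox genes. At 8 h it was 0.22 for anterior and 0.22 for central Hox genes, 0.21 for Hox non-coding transcripts, 0.37 for neural genes, 0.16 for retinoid targets and 0.16 for all Hox genes. At 36 h it was -0.39 for anterior, -0.59 for central and -0.64 for posterior Hox genes, -0.47 for non-coding transcripts, -0.50 for all Hox genes and 0.57 for pluripotency genes. The limma count of single windows was 0 for each of these differences, with 21 to 326 at an unadjusted p under 0.05.

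H3K27me3 was lower at 24 h over 37 windows in HoxA, Hoxa2 among them, and at Cyp26a1. SUZ12, the subunit of the complex that lays the mark, was lower over the same windows (median change -0.38, percentile 0 of 10000 sets matched on SUZ12 level, whose median was -0.13), so lower occupancy by that complex is a candidate explanation, on 1 array per time. A difference in amplitude between arrays cannot be told apart from it in part: with arrays scaled to the same spread the median change stayed between -1.01 and -0.46 over the 4 pairings of arrays, and the upper value missed the bound of -0.5 set for excluding it. The windows were chosen because they were lower, so their change itself was not tested. SUZ12 was also lower at 24 h over the posterior Hox windows (median change -0.27, 53 of 57 lower, percentile 10.2). There H3K27me3 was higher (median 0.24), so lower SUZ12 did not go with lower H3K27me3 throughout the clusters.

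H3K4me3 at 4, 8 and 36 h was near 0 at the start sites of the control genes. For loss of the mark after retinoic acid, the bound set against it was met. The lower array at 24 h had 0.43 there, above the highest of the 3 other times (0.18). The 2 arrays at 24 h lay farther apart than that (1.58 and 0.43), so loss is not excluded. It could also have been made good by 24 h and lost again. The GC trend as what brought these sites near 0 was argued against by its sign, since it added 0.16 to 0.20 there on each of the 3 arrays, and its removal, whose outcome that sign fixed, left -0.056. Lower enrichment of all marked sites alike may contribute and cannot be told apart: 36 other marked start sites had a median of 0.32 on these arrays (0.35, 0.26 and 0.38), between the bounds set for and against it. No biological explanation beyond the loss was tested.

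The second arrays of RARα and RARβ, uninduced and at 24 h, correlated with each other at a mean of 0.59, against 0.19 with the other 7 arrays of these antibodies. GC content was argued against, since the mean correlation was 0.57 after the GC trend was removed, and so was Polycomb-marked chromatin brought down in all 4, since it was 0.56 once SUZ12 was regressed out. For receptor binding at DR5 sites, the mean over the DR5 windows on these arrays lay at percentile 93.0 of random sets, short of the 95th. Just 16 of the 2357 windows hold such a site, so this mean cannot account for a correlation over all windows. A shared day or preparation by replicate number, which the labels do not give, stays open. The design gives no biological group that sets these 4 arrays apart.

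The count of RARβ windows at an unadjusted p under 0.05 was compared with the other splits of the 6 arrays. Of the 10 splits, 9 gave at least as many windows as the real one (47), the real one included, with a highest other of 176, and 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 replicate pairs, the highest other gave 59, and the splits that part 1 pair gave 65 to 176, so the arrays group by replicate number more than by treatment.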

How the results depend on the processing

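Centring on the control regions, removal of the GC trend, 10 kb windows, start sites as features, and the alternatives for lists other than the estimated correlation and for named start sites, as well as leaving out single arrays for lists, start sites and enriched windows, were chosen after the data were seen. Of the counts of changed windows, 163 of the results under an alternative stayed as reported and 10 moved, of the list results 544 stayed, 66 turned direction, 25 came to pass the test and 5 no longer passed, of the shifts over all Hox genes 69 stayed, 6 turned direction, 6 came to pass and 7 without a test moved, and of the start-site changes 306 stayed and 4 turned direction. The cause was not tested for any result below unless stated. For single windows, the count for H3K4me3 at 24 h was 12 with replicate number as a block, for H3K4me3 at 8 h 2 with centring on the control regions, for H3K27me3 at 24 h 2 in 10 kb windows, and for H3K27me3 at 36 h 45 with equal median absolute deviation and 10 in a fit of the 2 groups alone. Leaving out 1 array at a time gave 0 to 16 windows for H3K27me3 at 24 h, 0 to 11 at 8 h and 0 to 34 at 36 h, and 0 for every other antibody and time tested, with a lone array assumed to vary like the other groups. No paired analysis was possible because of single arrays for the 4, 8 and 36 h results and for the antibodies without replicates, while at 24 h the block on replicate number was fitted.

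Shifts of lists are given below as median log2 changes, and direction means that of the test, or the sign of the median where there was no test. With values as deposited, the shift came to pass the test for the H3K27me3 neural list (-0.15) and the H3K27me3 retinoid target list (-0.011). With arrays scaled to the same median absolute deviation, the shift came to pass the test for the H3K4me3 anterior Hox list (0.054) and the RARα median over the Hox genes (-0.029). There it turned direction for the H3K4me3 housekeeping list (-0.095), the RARβ anterior Hox list (-0.0041) and the RARγ Hox neighbour list (0.029). There it moved for the SUZ12 median over the Hox genes (-0.35). After quantile normalization, the shift came to pass the test for the H3K4me3 anterior Hox list (0.058), the H3K27me3 neural list (-0.15), the H3K27me3 retinoid target list (-0.0031) and the RARα median over the Hox genes (-0.042). There it turned direction for the H3K4me3 housekeeping list (0.078), the RARβ anterior Hox list (-0.0067), the RARγ Hox neighbour list (0.037) and the RARγ posterior Hox list (0.011). There it moved for the SUZ12 median over the Hox genes (-0.20). With the median of the probes of a window, the shift came to pass the test for the H3K27me3 retinoid target list (-0.013). There it turned direction for the H3K4me3 retinoid target list (-0.043), the H3K27me3 pluripotency list (0.018), the RARα mesoderm and endoderm list (-0.0041), the RARα retinoid target list (-0.020), the RARγ Hox neighbour list (0.045), the RARγ Hox non-coding list (0.0036), the RARγ mesoderm and endoderm list (-0.033), the RARγ neural list (-0.049) and the NCoR median over the Hox genes (-0.0090). There it moved for the RNA polymerase II median over the Hox genes (0.040) and the SUZ12 median over the Hox genes (-0.31). With centring on the control regions, the shift came to pass the test for the H3K4me3 anterior Hox list (-0.0042), the H3K27me3 neural list (-0.20) and the H3K27me3 retinoid target list (-0.052). There it turned direction for the RARβ anterior Hox list (-0.035) and the RNA polymerase II median over the Hox genes (-0.035). There it moved for the RXRα median over the Hox genes (-0.025). With the GC trend removed, the shift came to pass the test for the H3K4me3 anterior Hox list (0.037) and the H3K4me3 median over the Hox genes (0.014). There it turned direction for the RARβ anterior Hox list (-0.013), the RARγ mesoderm and endoderm list (-0.046), the RARγ neural list (-0.091) and the RARγ median over the Hox genes (-0.016). There it moved for the SUZ12 median over the Hox genes (-0.23) and the RXRα median over the Hox genes (-0.034). With an estimated correlation, the shift no longer passed for the H3K4me3 pluripotency list (-0.65), the H3K27me3 anterior Hox list (-0.11) and the H3K27me3 posterior Hox list (0.24). With replicate number as a block, the shift came to pass the test for the H3K4me3 anterior Hox list (0.029), the H3K27me3 neural list (-0.13) and the H3K27me3 retinoid target list (0.0080). There it turned direction for the RARα housekeeping list (0.0023), the RARα posterior Hox list (0.015), the RARβ anterior Hox list (-0.014) and the RARγ posterior Hox list (0.0097).

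H3K4me3 medians without single arrays ran from -1.23 to 0.70 for the housekeeping list, 0.069 to 0.090 for the anterior Hox list, -0.068 to 0.20 for the central Hox list, -0.34 to 0.055 for the Hox neighbour list, -0.11 to 0.21 for the Hox non-coding list, -0.26 to 0.041 for the posterior Hox list, -0.21 to 0.030 for the neural list, -1.46 to 0.10 for the pluripotency list, -0.21 to 0.25 for the retinoid target list, -0.066 to 0.087 for the Hox genes. H3K27me3 medians without single arrays ran from -0.47 to 0.29 for the housekeeping list, -0.22 to 0.14 for the central Hox list, 0.037 to 0.27 for the Hox neighbour list, 0.095 to 0.41 for the posterior Hox list, -0.19 to 0.19 for the pluripotency list, -0.043 to -0.0021 for the retinoid target list, -0.089 to 0.18 for the Hox genes. RARα medians without single arrays ran from 0.0023 to 0.18 for the housekeeping list, -0.045 to 0.052 for the anterior Hox list, 0.029 to 0.13 for the Hox neighbour list, -0.024 to 0.10 for the Hox non-coding list, -0.065 to 0.027 for the posterior Hox list, -0.059 to 0.020 for the retinoid target list. RARβ medians without single arrays ran from -0.064 to 0.047 for the anterior Hox list, -0.020 to 0.10 for the central Hox list, -0.11 to 0.082 for the Hox non-coding list, -0.029 to 0.15 for the mesoderm and endoderm list, -0.028 to 0.14 for the neural list, -0.0017 to 0.073 for the Hox genes. RARγ medians without single arrays ran from -0.12 to 0.043 for the Hox neighbour list, -0.092 to 0.059 for the posterior Hox list, -0.14 to 0.14 for the mesoderm and endoderm list, -0.090 to 0.18 for the neural list. For single start sites they ran from -0.086 to 0.29 for H3K27me3 at Sox3 and from -1.40 to 0.38 for H3K4me3 at Sox2.

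Counts of enriched windows follow their threshold by construction. At thresholds of 1.5 and 0.5 they were 8 and 140 for H3K4me3 uninduced, 0 and 114 at 24 h, 7 and 582 for H3K27me3 uninduced, 67 and 539 at 24 h, 47 and 472 for SUZ12 uninduced and 4 and 381 at 24 h. With equal median absolute deviation they were 18 and 63 for H3K4me3 uninduced and at 24 h and 91 for H3K27me3 uninduced. Leaving out 1 array gave 47 to 292 and 22 to 283 for H3K4me3 uninduced and at 24 h and 245 to 503 for H3K27me3 uninduced. At a simulated log2 change of 1 the test recovered 1 of 200 windows for H3K4me3, 34 for H3K27me3 and 96 to 156 for the receptors, and the cause was not tested. What signal over background limits was not measured.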

Other observations

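The gene groups below were put together after the array's region labels were seen, and the test of DR5 sites was set before its result was seen. Genes of the Polycomb complexes were themselves marked by H3K27me3 in part. Among 17 with a start site on the array, those above 0.5 in uninduced cells included Bmi1 (1.19 ± 0.33, n = 2), Cbx8 (0.83 ± 0.05) and Sfmbt2 (0.68 ± 0.58). At 24 h they had 1.27 ± 0.32, 1.05 ± 0.03 and 0.96 ± 0.39. None of 11 genes of H3K4 methyltransferase complexes, 13 genes of the INO80 chromatin remodelling complex or 9 control genes was above 0.5, the highest in each group being -0.01, 0.15 and -0.21. Of 7 homeobox genes of the TALE class, whose proteins bind DNA together with Hox proteins, Meis1 (1.06 ± 0.34) and Meis2 (0.80 ± 0.23) were above 0.5 and had 1.00 ± 0.40 and 0.64 ± 0.29 at 24 h. The smallest adjusted p among these genes in limma was 0.996 for H3K27me3 and 0.999 for H3K4me3.

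The HoxA windows near Gm15055 that were strongest for NCoR, RARα and, uninduced and at 24 h, RXRα were also high for SUZ12. In the window 52049000 to 52049999 on chromosome 6 SUZ12 had 1.64 uninduced, 1.32 at 2 h and 1.69 at 24 h, while H3K27me3 had -0.32 and -0.26 and H3K4me3 -0.26 and -0.12, uninduced and at 24 h. The RAR arrays differed widely there, from -0.74 to 4.21 over the 3 RARα arrays at 24 h and from -0.65 to 4.64 over the 3 RARβ arrays. The window held 40 probes and 43% GC, with no DR5 site inside it, and the nearest start site was that of Gm15055 at 2949 bp. A DR5 site lay nearby at 52051469 to 52051485, in a window where the mean over the RAR and RXRα arrays was -0.10.

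Receptor signal may be higher where the DNA holds a DR5 site. Over all 19 RAR and RXRα arrays, the mean of the 16 windows with such a site was 0.13 and lay at percentile 99.1 of 10000 random window sets, above the bound set beforehand, and at 99.6 once the GC trend was removed. By group the percentile was 98.2 for RARα uninduced, 99.98 for RARα at 24 h, 78.5 and 61.3 for RARβ, 81.3 and 99.8 for RARγ, and 97.0, 81.3 and 93.5 for RXRα uninduced, at 2 h and at 24 h. The higher of these windows included 1 near Hoxb1 (chromosome 11, 96234000 to 96234999, mean 0.37). The lowest of the 16 lay near Gm15055 (chromosome 6, 52051000 to 52051999, mean -0.10). The array's regions were chosen by the study, so the random sets stand for this array and not for the genome.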
